A study of Drosophila melanogaster with 6 samples.

How the data were processed

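RNA was measured in 6 midgut samples of w1118 females, 3 virgin and 3 mated, each a pool of 30 guts. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded TruSeq kit that selects polyadenylated mRNA. Per the submitters' processing notes, CASAVA 1.8.4, STAR with no version given, DESeq2 1.42.0 and the genome build dm6 were used, with no role or order stated; the annotation release is not given in the sources used here. The deposited values are raw read counts per gene, 1 file per sample in the layout of STAR's gene counts, with 3 count columns (unstranded, forward and reverse strand) and 4 summary rows. In that layout the authors' counts hold reads placed at 1 position, so members of near-identical gene families are under-counted. No normalization by the authors was found in the values.

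The kit reads the strand opposite to the RNA, so the reverse-strand column was used; the forward-strand column held 1.86% to 2.32% of the counts of both columns. The 4 summary rows stayed out of library sizes and tests. Unmapped reads made up 9.13 ± 2.15% of virgin and 9.21 ± 3.64% of mated libraries (SD, n = 3 each), reads in no gene 6.97 ± 2.06% and 6.42 ± 1.92%, and ambiguous reads 1.24 ± 0.0546% and 1.20 ± 0.0506%. The files pair no identifiers with the gene symbols. Positions come from the Ensembl annotation of the fly genome release that dm6 holds; 17047 of 17116 symbols and 8583 of 8607 tested symbols matched. Older symbols in the gene lists were resolved through RefSeq synonyms.

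Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr left 8607 genes, TMM factors ranged from 1.04 to 1.13 in virgin and from 0.86 to 0.965 in mated libraries, and glmQLFit with robust dispersion was followed by glmQLFTest (two-sided, group as the only term). The common biological coefficient of variation was 0.291. Genes passed at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes. Levels are CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries, and log2 fold changes are given with standard errors derived from the F statistic. The labels do not say whether the pools came from separate cultures, so p-values measure the spread between these samples. Floors cover counting error only, whereas the standard errors include the spread between libraries. A fold against a group at 0 used a floor of 3 counts over the group.

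Gene lists of cell types and processes, 41 in all, were written before the data were examined, as were the comparison, the rule for naming genes and all but 1 of the other settings. The 37 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over these lists. With an estimated correlation, 0 of the 11 lists that passed kept their call, and 5 of 37 had an unadjusted p below 0.05; fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, passed 7, and its mixed test, for change in either direction, 22. The list of mitochondrially encoded genes was not analysed here. Genes named in the text are the 10 largest rises and 10 largest falls among passing genes with at least 5 CPM in the higher group and groups that do not overlap; up to 4 members of each list with the smallest adjusted p, or the 2 highest by CPM where none passed; and SREBP, FASN1, bgm, Kr-h1, esg, Dl, AstC, Tk, Dh31, PCNA, CycB, upd3, Yp1, vas and Mhc. DptA, osk, to, Try29F, Mal-A7 and the genes of the closing section that fall outside this rule were chosen after their values were seen.

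The pipeline was tested on simulated counts for 8607 genes, drawn from the real means and library sizes. For this comparison it recovered 2% of 50 genes changed 1.5-fold, 64% of 50 changed 2-fold, 84% of 50 changed 4-fold and 94% of 50 changed 8-fold, with 6 unchanged genes among 131 calls. Most simulated changes of 1.5-fold were thus missed.

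Alternatives were RLE, upper-quartile and library-size scaling, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, the unstranded column, each library left out in turn, a threshold of 0.01, a minimum fold of 1.5, an estimated inter-gene correlation, fry, and genes of other tissues left out. Leaving out virgin 2 and mated 1 together was added after seeing the data. Single measures of the libraries were compared by exact permutation tests.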

Results

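Gene expression was measured by RNA sequencing in the midgut, the main digestive and absorptive part of the fly intestine, of virgin and mated Drosophila melanogaster females. The flies were of the w1118 strain, a white-eyed laboratory stock used as wild type, and were 8 days old. Mated females were taken 3 days after mating. Each sample pooled 30 guts, and there were 3 virgin and 3 mated samples. Gene counts per library, in units of 1e6, ranged from 15.9 in virgin 3 to 29.0 in virgin 1, with 16.3 to 25.5 in the mated libraries. Genes with at least 1 count numbered 9250 ± 146 in virgin and 9859 ± 332 in mated libraries (SD, n = 3 each). Libraries of the same group differed by more than sampling noise in all 6 pairs, with a chi-square per degree of freedom of at least 24.4, so no pair was taken as 1 library given more than once.

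The comparison asked how the intestine of females differs after mating. In mated midguts, digestive proteases of the Jonah family rose by up to 5.47-fold, together with the lysozyme LysB, the fat-handling genes bmm, Lsd-1 and FASN1, and muscle genes such as Act57B. The sugar-digesting enzymes tobi, Mal-A8 and Mal-A1 fell by 7.58-fold, 4.17-fold and 2.72-fold, and the cytochrome P450 Cyp28d1, an enzyme of a family that oxidises small molecules, fell by 6.81-fold. No member of the progenitor cell list and no member of the DNA replication and mitosis list passed the test.

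Of 8607 genes tested, 353 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 213 higher and 140 lower in mated midguts. All 353 had 3 mated libraries on 1 side of the 3 virgin libraries, as did 23.9% of all tested genes, where chance gives 10%. Changes over 2-fold were seen in 106 of the higher and 53 of the lower genes. Scaling by library size alone, which moved the median log2 fold change of all genes from -0.05 to -0.30, gave 146 higher and 726 lower genes, so the share of higher calls was 16.7% in place of 60.3%. The count fell to 225 without virgin 2, to 169 without mated 2 and to 191 without mated 3, and 127 genes (86 higher, 41 lower) passed in all 6 fits that left out 1 library.

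**Figure D1:**
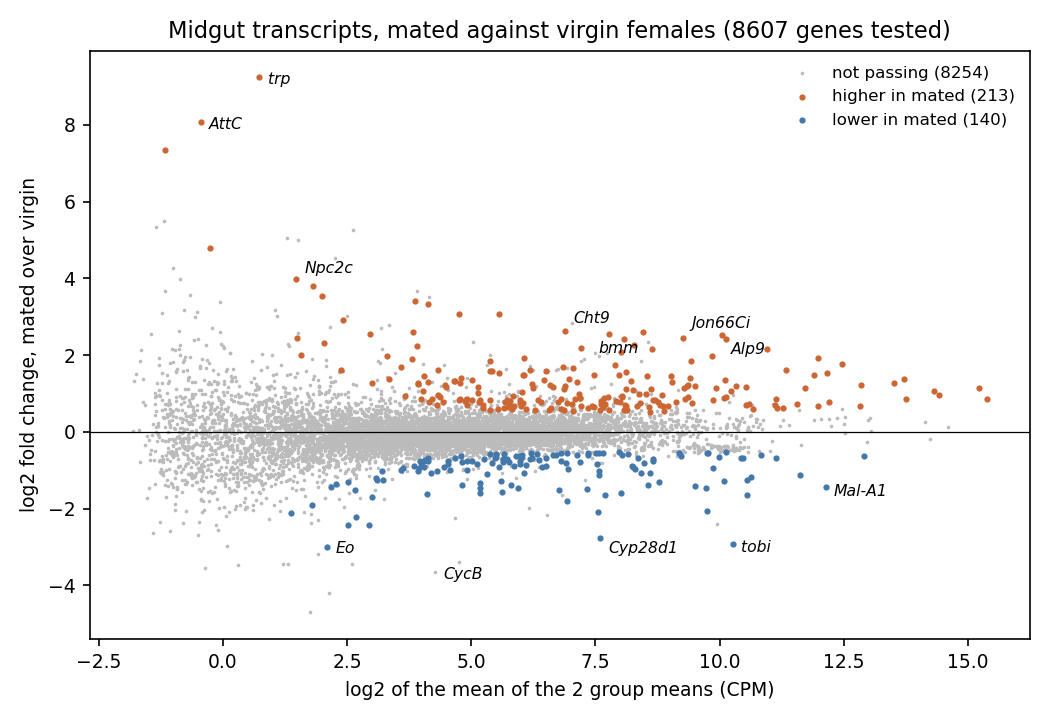
Each point is 1 of the 8607 tested genes, with the log2 of the mean of both group means in CPM on the x axis and the log2 fold change of mated over virgin on the y axis. Orange points are the 213 genes higher in mated midguts and blue points the 140 lower; fitted values of genes with 0 counts in all virgin libraries, such as trp and AttC, depend on the prior count.

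Digestive proteases of the Jonah family were higher in mated midguts. Of the 16 Jonah genes, which encode secreted serine proteases of the gut, 12 rose, 0 fell and 4 did not pass, and 14 were higher when adjusted over the list alone. Jon66Ci (3L, 8391540 to 8392377) went from 190 ± 27.7 to 1041 ± 152 CPM (SD, n = 3 each), a log2 fold change of 2.45 ± 0.17 (SE; adjusted p = 1.74e-05). Jon44E (2R, 8691448 to 8692844) rose 4.84-fold, Jon65Ai (3L, 6053493 to 6054443) 4.49-fold and Jon99Fi (3R, 30488963 to 30489895) 3.78-fold. Jonah transcripts made up 8.59 ± 0.769% of gene counts in virgin and 15.8 ± 0.909% in mated libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries can give). The list's median log2 fold change was 1.33 (camera adjusted p = 8.74e-44; adjusted p = 0.165 with an estimated correlation). Between 10 and 12 members passed when any 1 library was left out. Of 11 trypsin-like proteases tested, 3 rose and 8 did not pass, also when adjusted over the list alone. These were deltaTry, at 5.76 ± 2.65 CPM in virgin and 47.8 ± 10.5 CPM in mated libraries, and the abundant epsilonTry (1.71-fold) and thetaTry (1.51-fold). Among the 8, Try29F had 49.2 ± 54.4 and 4.64 ± 2.16 CPM, with 111 CPM in virgin 2 (log2 fold change -3.40 ± 1.15, adjusted p = 0.257); 1 member was lower at an unadjusted p below 0.05 and 1 in DESeq2. The trypsin list passed (median 0.20, camera adjusted p = 0.00639), not with an estimated correlation (adjusted p = 0.474 with an estimated correlation), nor with fry (adjusted p = 0.0578), nor without virgin 2 (adjusted p = 0.0724), and its median was -0.06 when scaled by library size alone. Only 1 member, deltaTry, passed without mated 2 or without mated 3; epsilonTry was lost in these fits (adjusted p up to 0.0639) and thetaTry in all such fits but that without virgin 1 (up to 0.0995). Scaled by library size alone, thetaTry did not pass either (adjusted p = 0.0612). Many of these protease genes lie in tandem copies and the authors' counts hold uniquely placed reads, so the split between near-identical neighbours is uncertain; reads placed at several positions made up 4.73 ± 0.366% of virgin and 6.75 ± 1.01% of mated libraries.

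Of the antimicrobial genes, LysB (3L, 1207371 to 1207981), a lysozyme that cuts bacterial cell walls, rose from 1271 ± 347 to 3897 ± 394 CPM (log2 fold change 1.62 ± 0.20, adjusted p = 0.00137), and the 5 other tested lysozymes did not pass. The lysozyme list had a median of 1.13 (camera adjusted p = 0.0088, or 0.33 with an estimated correlation), with 1 member passing also when adjusted over the list alone. When 1 library was left out, 1 or 2 members passed. In the list of antimicrobial peptides and the Imd pathway, an immune pathway of the gut, 2 of 17 genes rose and 15 did not pass, with the same count adjusted over the list alone. They were PGRP-SC2, a peptidoglycan-cleaving amidase (1.54-fold), and the peptide AttC, which had 0 counts in the virgin and 81 in the mated libraries and was at least 38.2-fold higher against a floor of 3 counts over the group. The list's median was 0.99, with AttC fitted or at its bound (camera adjusted p = 4.44e-06; adjusted p = 0.165 with an estimated correlation). Mated 2 held the highest level of DptA, at 24.8 CPM. PGRP-SC2 did not pass without virgin 2, virgin 3, mated 2 or mated 3 (adjusted p up to 0.106), nor AttC without virgin 1, mated 2 or mated 3 (up to 0.167).

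Among carbohydrate-digesting enzymes, more genes fell than rose. Of 20 tested, 6 were lower, 2 higher and 12 did not pass; 7 were lower and 5 higher when adjusted over the list alone. The glucosidase tobi (3R, 25344761 to 25346921) went from 2185 ± 839 to 288 ± 102 CPM (log2 fold change -2.92 ± 0.36, adjusted p = 0.00646). The maltases Mal-A8 (2R, 8471954 to 8473961), Mal-A6 (2R, 8465158 to 8467595) and Mal-A1 (2R, 8449664 to 8451904), which split disaccharides, had log2 fold changes of -2.06 ± 0.29, -1.65 ± 0.19 and -1.44 ± 0.19. With the replicate number as a block, tobi and Mal-A8 did not pass (adjusted p of 0.101 and 0.129), though both passed in all 6 fits that left out 1 library. The amylase-related gene Amyrel fell 5.35-fold, but did not pass without virgin 1, virgin 2, mated 2 or mated 3 (adjusted p up to 0.199), nor with no low-count filter, limma-voom or the unstranded column. Mal-A7 had 1657 CPM in virgin and 313 CPM in mated libraries and did not pass (adjusted p = 0.0593). Both higher members were alpha-mannosidases, which cut mannose from glycoproteins; LManVI rose 2.21-fold. The number higher was 1 without virgin 1 or mated 3 and 5 without virgin 3, and the number lower 4 without virgin 1, virgin 2, mated 2 or mated 3 and 9 without mated 1. The list's median was -0.60 (camera adjusted p = 0.00336; adjusted p = 0.474 with an estimated correlation), and it did not pass with limma-voom (median -0.33, adjusted p = 0.0767) or fry (adjusted p = 0.0913).

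Of 65 cytochrome P450 genes, 7 fell, 1 rose and 57 did not pass, and 9 were lower and 2 higher when adjusted over the list alone. Cyp28d1 (2L, 5210460 to 5212445) went from 337 ± 78.8 to 49.5 ± 7.05 CPM (log2 fold change -2.77 ± 0.19, adjusted p = 1.74e-05). Cyp6g1, known for its part in insecticide resistance, and Cyp12d1-p fell 3.03-fold and 3.02-fold, whereas Cyp4ad1 rose 2.18-fold. The list's median was -0.25 (camera adjusted p = 0.00399; adjusted p = 0.217 with an estimated correlation). The number lower was 4 without virgin 1 or virgin 2 and 3 without mated 2 or mated 3, and 16 when scaled by library size alone. Glutathione S-transferases, which conjugate small molecules, went both ways, with 2 of 31 higher (GstD2 and GstD9), 2 lower (GstT4 and GstO2) and 27 not passing, or 5 higher and 2 lower when adjusted over the list alone. GstT4 fell 2.48-fold and passed in every fit that left out 1 library. GstD2 passed only without mated 3 (adjusted p up to 0.238 in the other fits) and not with limma-voom or no low-count filter, GstO2 in none (up to 0.132), and GstD9 was lost without virgin 2, virgin 3 or mated 2 (up to 0.0664).

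Fat-handling genes changed individually, and their lists did not pass camera. In fry's mixed test, for change in either direction, the synthesis list and the storage and export list passed (adjusted p of 0.00184 and 0.00364). That test passed 22 of all 37 lists. FASN1 (2L, 3056598 to 3068177), a fatty acid synthase, rose from 193 ± 24.3 to 416 ± 59.4 CPM (log2 fold change 1.11 ± 0.15, adjusted p = 0.00208), and the acyl-CoA synthetase bgm (2L, 14013004 to 14019328) rose 1.86-fold. The phosphatidate phosphatase Lpin rose by 0.51 on the log2 scale, but its call was lost in each fit that left out 1 library (adjusted p up to 0.172) and when scaled by library size alone (adjusted p = 0.183). SREBP, a transcription factor that controls lipid synthesis genes, had 217 ± 36.2 and 258 ± 22.1 CPM and did not pass (adjusted p = 0.431). In all, 3 of 15 genes of fatty acid and triglyceride synthesis rose and 12 did not pass, also over the list alone (camera adjusted p = 0.15). Its median of 0.09 turned to -0.16 when scaled by library size alone. Among 12 genes of lipid storage and export, the triglyceride lipase bmm (3L, 14776496 to 14786412) rose from 110 ± 34.0 to 366 ± 22.2 CPM (log2 fold change 1.74 ± 0.22, adjusted p = 0.00168). The lipid droplet protein Lsd-1 rose 3.78-fold and the lipoprotein receptor LpR1 1.92-fold, whereas Mcad, an enzyme of fatty acid oxidation, fell 1.86-fold and 8 did not pass; adjusted over the list alone, 3 were higher and 3 lower. That list did not pass camera (adjusted p = 0.191), with a median of -0.04, a mean of 0.09 and a test direction of higher. Mcad did not pass without mated 2 or mated 3 (adjusted p up to 0.0632), nor in the unstranded column (adjusted p = 0.73).

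Of 15 lipases and sterol-uptake genes tested, CG17192 rose 2.28-fold, CG8093 fell 2.78-fold and mag by 0.68 on the log2 scale, and 12 did not pass (list adjusted p = 0.733); 2 were higher and 2 lower when adjusted over the list alone. CG8093 did not pass without virgin 3, mated 2 or mated 3 (adjusted p up to 0.101), nor mag without virgin 1, virgin 2, mated 2 or mated 3 (up to 0.181). In the metal list, the metallothionein MtnC fell from 312 ± 88.6 to 99.8 ± 11.9 CPM, while both ferritin chains rose, Fer2LCH 1.64-fold and Fer1HCH 1.55-fold, along with the zinc transporter Zip89B (3.05-fold); 13 of 17 did not pass, and the counts adjusted over the list alone were also 3 higher and 1 lower. That list's median was 0.10, or -0.16 when scaled by library size alone, its mean was -0.10 and its test direction was higher (camera adjusted p = 0.733). Of the 3 rises, 0 passed without mated 2 and 1 without mated 3; Fer2LCH was lost without mated 2 only (adjusted p = 0.0524), Fer1HCH also without virgin 2, virgin 3 or mated 3 (up to 0.0995), and Zip89B without virgin 1 or any mated library (up to 0.103). Of 15 sugar and amino acid transporters, 1 rose, the amino acid transporter slif (1.98-fold), or 3 when adjusted over the list alone; the list's test direction was higher, against a median of -0.03 and a mean of -0.10 (list adjusted p = 0.601). The mucin Muc55B rose 2.45-fold, the only one of 6 tested genes of the peritrophic matrix list to pass, also adjusted over the list alone (list adjusted p = 0.186, or 0.0281 with fry); it did not pass without mated 2 or mated 3 (adjusted p up to 0.0607).

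**Figure D2:**
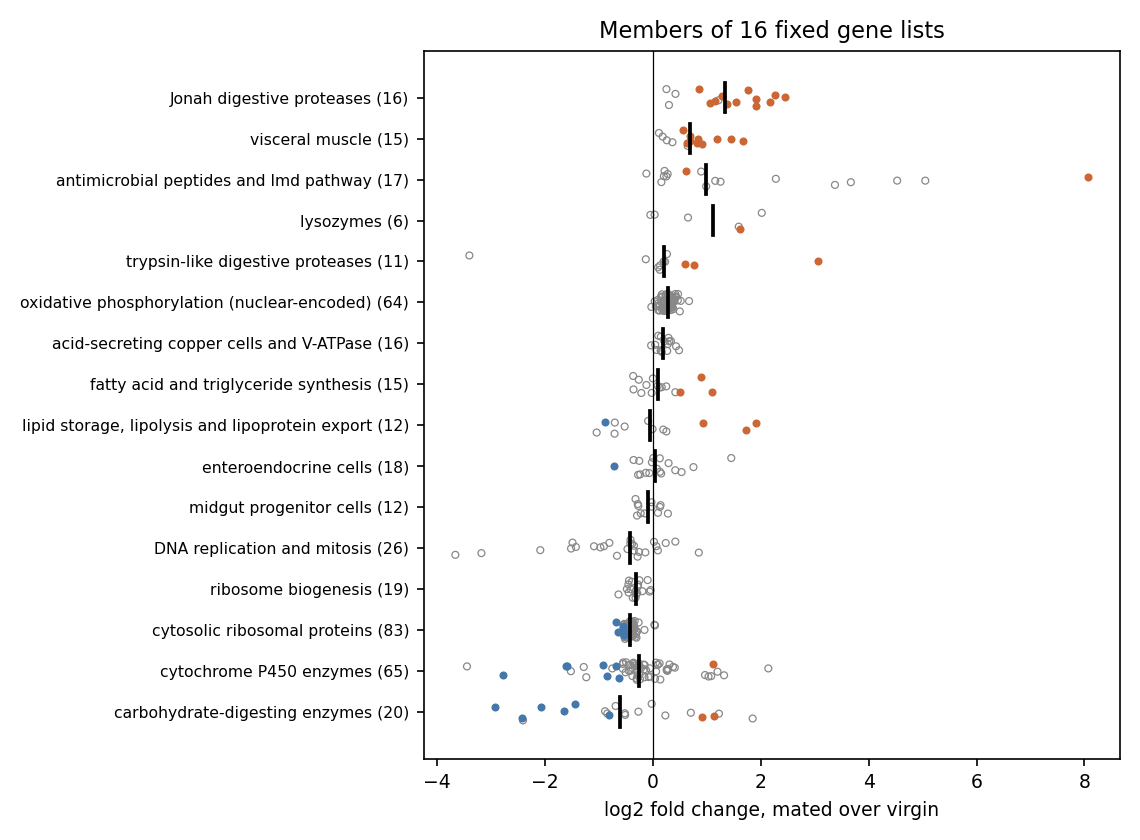
Each point is a tested member of 1 of 16 gene lists, with the number of tested members in brackets and the log2 fold change of mated over virgin on the x axis; filled points passed the test (orange higher, blue lower) and black bars are list medians. The Jonah median lies at 1.33 and that of the cytosolic ribosomal proteins at -0.43; the medians of the fatty acid, enteroendocrine, V-ATPase and trypsin lists change sign when scaled by library size alone.

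Transcripts of visceral muscle, the muscle layer around the gut tube, were higher in mated samples. Of 15 muscle genes, 10 rose, 0 fell and 5 did not pass, and 12 were higher when adjusted over the list alone. Act57B (2R, 20944021 to 20946431), a muscle actin, went from 276 ± 51.4 to 756 ± 176 CPM (log2 fold change 1.45 ± 0.20, adjusted p = 0.00195). Act87E rose 3.20-fold, the muscle LIM protein Mlp60A 2.27-fold and Mhc, the muscle myosin heavy chain, 1.88-fold. The list's median was 0.68 (camera adjusted p = 6.67e-14; adjusted p = 0.355 with an estimated correlation). The number of members passing was 8 without mated 3, 6 without virgin 1, 5 without mated 1 and 4 without virgin 2, virgin 3 or mated 2; Mhc did not pass in the last 3 (adjusted p up to 0.0585). Scaled by library size alone, 5 members passed. Basement membrane genes Ppn (1.69-fold) and SPARC (1.82-fold) rose and 8 others did not pass, also adjusted over the list alone (list adjusted p = 0.1); SPARC lost its call in the unstranded column (adjusted p = 0.0517) and in all such fits but the one without virgin 1 (adjusted p up to 0.198). Neither gene passed when scaled by library size alone (adjusted p of 0.0514 for Ppn and 0.0817 for SPARC).

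Cytosolic ribosomal protein genes were lower as a group. Of 83 tested, 7 fell, 0 rose and 76 did not pass, whereas 66 were lower when adjusted over the list alone. RpL41 (2R, 24903416 to 24903935) went from 1704 ± 96.2 to 1064 ± 63.2 CPM (log2 fold change -0.68 ± 0.13, adjusted p = 0.0131), and RpL27, RpL5 and RpL21 fell 1.57-fold, 1.51-fold and 1.47-fold. The list's median was -0.43 (camera adjusted p = 1.05e-18; adjusted p = 0.701 with an estimated correlation), and it did not pass with fry (adjusted p = 0.0913). No member passed in edgeR without mated 2 or without mated 3, and 1 passed without virgin 1, virgin 2 or virgin 3. RpL41 was lost without virgin 3, mated 2 or mated 3 (adjusted p up to 0.084), and RpL27, RpL5 and RpL21 in more of these fits (up to 0.145, 0.148 and 0.18); RpL21 was also lost with RLE scaling (adjusted p = 0.0647) and a filter of 1 CPM (adjusted p = 0.054). The number lower was 3 in these 2 fits, 14 with upper-quartile scaling and 79 when scaled by library size alone. In the full data 71 had an unadjusted p below 0.05 and DESeq2 and limma-voom called 29 and 10. The share of counts from these genes was 9.12 ± 0.515% in virgin and 5.62 ± 0.361% in mated libraries (exact permutation p = 0.1, two-sided). Of 19 genes of ribosome biogenesis, 0 passed in edgeR, also adjusted over the list alone, with 3 below an unadjusted p of 0.05 and 1 called by DESeq2 and by limma-voom. That list passed as a group (median -0.32, camera adjusted p = 0.00586; adjusted p = 0.701 with an estimated correlation), but not without virgin 2 (adjusted p = 0.138) or with fry (adjusted p = 0.322), and 1 member passed without virgin 1 or mated 3. Scaled by library size alone, Myc and Non1 were lower (adjusted p of 0.0143 and 0.00792), and Myc also with no low-count filter (adjusted p = 0.031).

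Nuclear genes of oxidative phosphorylation lay in the other direction. None of 64 passed in edgeR, also adjusted over the list alone, 15 had an unadjusted p below 0.05, DESeq2 called 1 and limma-voom 0. Positive values were seen in 63, with a median of 0.29 that was 0.03 when scaled by library size alone (camera adjusted p = 1.01e-06; adjusted p = 0.701 with an estimated correlation). The list did not pass without virgin 2 and mated 1 together (adjusted p = 0.354) or with fry (adjusted p = 0.322). The V-ATPase and copper cell list, for acid secretion, also passed with no member called by edgeR, overall or adjusted over the list alone (3 of 16 below an unadjusted p of 0.05, DESeq2 1, limma-voom 0). Its median was 0.19, or -0.06 when scaled by library size alone, where it did not pass (camera adjusted p = 0.0257; adjusted p = 0.701 with an estimated correlation); it did not pass either with fry (adjusted p = 0.214) or without virgin 2, virgin 3 or mated 1 (adjusted p of 0.164, 0.106 and 0.0881).

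**Figure D3:**
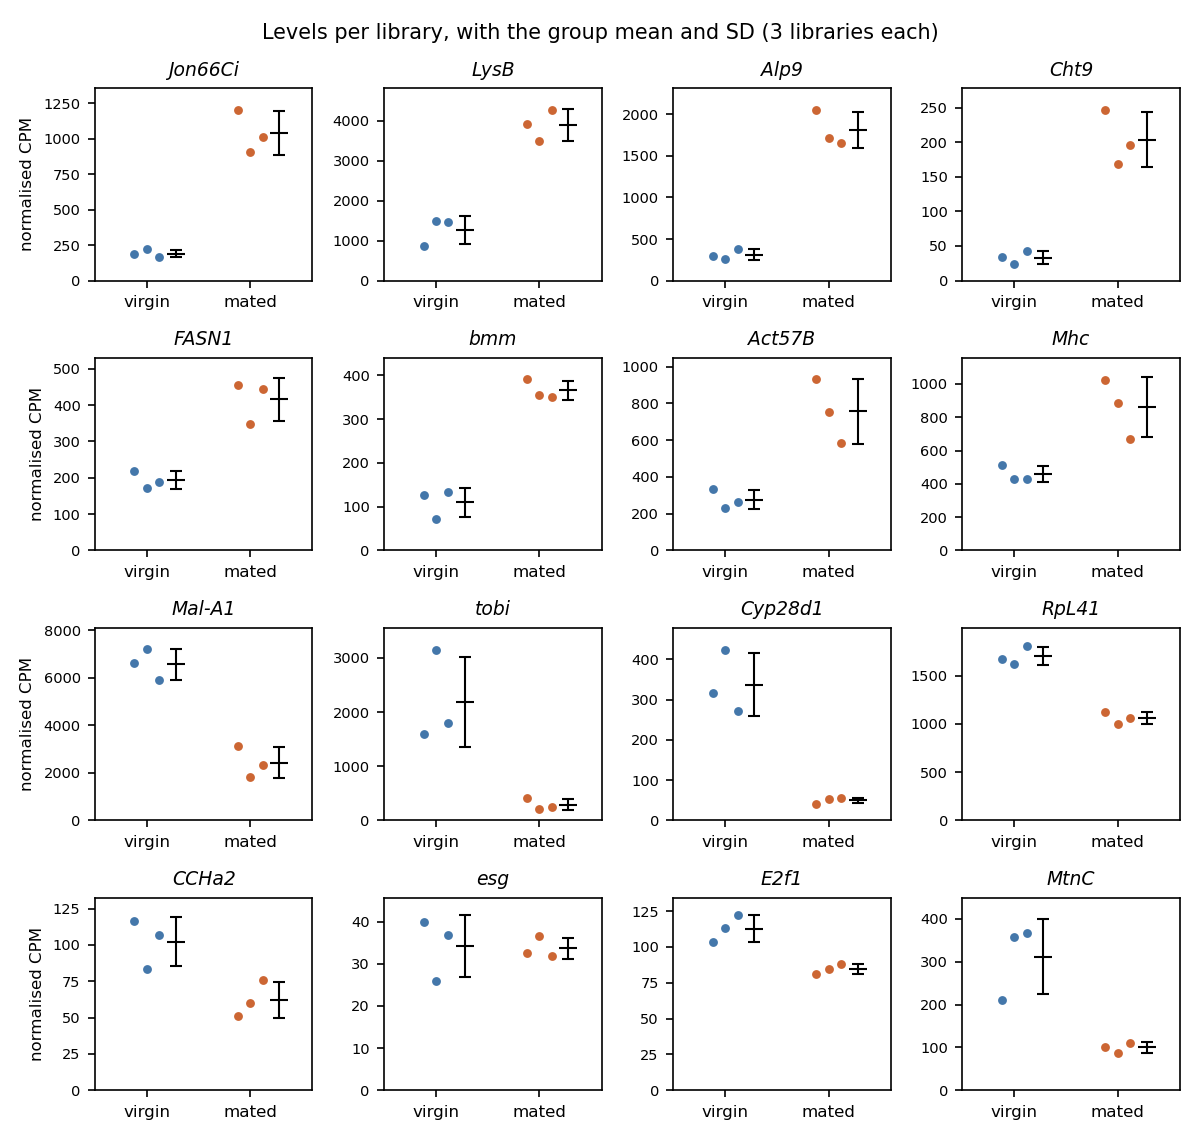
Normalised CPM of 16 genes in each library, with points for the 3 virgin (blue) and 3 mated (orange) libraries and a bar for the group mean with its SD. In 15 of the panels the groups do not overlap; in that of esg, which did not pass, they do.

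Few markers of midgut cell types passed, in a test that missed most simulated changes of 1.5-fold. None of 12 progenitor genes passed in edgeR, also adjusted over the list alone, and 0 had an unadjusted p below 0.05 or a call by DESeq2 or limma-voom. Among them esg, a transcription factor of stem cells and enteroblasts, had 34.2 ± 7.35 and 33.7 ± 2.58 CPM, and Dl, the Notch ligand of stem cells, had an adjusted p of 0.982. Of 18 enteroendocrine genes, the peptide hormone CCHa2 fell 1.65-fold and 17 did not pass; adjusted over the list alone, 1 was higher and 1 lower. CCHa2 did not pass without virgin 1, virgin 3, mated 1 or mated 2 (adjusted p up to 0.166), nor with RLE scaling (adjusted p = 0.0552). The peptides AstC, Tk and Dh31 had adjusted p values of 0.722, 0.375 and 0.231; Tk was lower when scaled by library size alone (adjusted p = 0.0315) and Dh31 higher without virgin 1 (adjusted p = 0.0299). None of 8 enterocyte genes passed in edgeR, also adjusted over the list alone, with 2 below an unadjusted p of 0.05 and 0 called by DESeq2 or limma-voom. Of these 3 lists, none passed camera (adjusted p of 0.678, 0.772 and 0.244).

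Of 26 genes of DNA replication and mitosis, 0 passed in edgeR, also adjusted over the list alone, 3 had an unadjusted p below 0.05 and 0 were called by DESeq2 or limma-voom. Scaled by library size alone, 2 were lower, among them E2f1 (log2 fold change -0.67, adjusted p = 0.0137). PCNA, a replication clamp, had 5.15 ± 2.18 and 4.70 ± 0.555 CPM. CycB, a mitotic cyclin, stood at 103 CPM in virgin 2 and at most 3.63 CPM in the other 5 libraries. Virgin 2 also held oocyte transcripts, with osk at 22.7 CPM against at most 0.127 CPM elsewhere. The list did not pass with all libraries (median -0.41, adjusted p = 0.191), and passed as lower without virgin 1 (adjusted p = 0.0018) or virgin 3 (adjusted p = 0.022), fits in which virgin 2 was 1 of 2 virgin libraries.

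Lists of other tissues served to look for carry-over. A test between the groups cannot show tissue carried into a single pool or equally into both groups. Genes with counts in few libraries did not enter it. Of 27 ovary genes, 4 were tested, and the untested ones held 1230 counts in the virgin and 58 in the mated libraries. No gene of the neuron (4 tested), trachea (5), fat body (6), ovary (4), hindgut (2) or haemocyte (2) lists passed in edgeR, DESeq2 or limma-voom. At an unadjusted p below 0.05 there was 1 fat body and 1 hindgut gene, and adjusted over the list alone 1 hindgut gene was lower and 0 passed in the other 5. Without virgin 3, the fat body gene Fst was higher (log2 fold change 1.46, adjusted p = 0.00411, against 0.72 and 0.581 with all libraries). Scaled by library size alone, 1 fat body gene and the hindgut gene bowl (adjusted p = 0.0204) were lower. The fat body gene to, too low in most libraries to be tested, had 734 of its 736 mated counts in mated 1 and 140 of its 143 virgin counts in virgin 2. The lists with at least 3 tested genes had camera adjusted p values of 0.579 (neurons, or 0.0432 with fry, as lower), 0.94 (trachea, with a median of -0.06, a mean of -0.01 and a test direction of higher), 0.734 (fat body) and 0.734 (ovary). Of 7 Malpighian tubule genes, the renal organ of the fly, urate oxidase Uro rose, from 2.46 ± 1.23 to 26.9 ± 16.1 CPM, and 6 did not pass, also adjusted over the list alone (list adjusted p = 0.151, or 0.0349 without virgin 2). Uro did not pass without virgin 1, virgin 2, virgin 3 or mated 2 (adjusted p up to 0.134), nor with limma-voom (adjusted p = 0.0887) or no low-count filter (adjusted p = 0.0936). None of 9 male seminal fluid genes had enough counts to be tested, with 20 counts in all virgin and 13 in all mated libraries. The yolk protein gene Yp1, made in fat body and ovary, had 93.4 ± 53.7 and 58.0 ± 29.1 CPM (adjusted p = 0.656), and vas was too low in most libraries to be tested.

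Hormone and signalling lists did not pass camera. In fry's mixed test, for change in either direction, the juvenile hormone, ecdysone, insulin and EGFR lists passed (adjusted p of 0.00578, 0.0038, 0.0043 and 0.0272). The JAK/STAT list did not (adjusted p = 0.264), and 22 of all 37 lists passed that test. None of 7 juvenile hormone genes passed in edgeR over all genes, with 3 below an unadjusted p of 0.05, 1 lower when adjusted over the list alone, 1 called by DESeq2 and 0 by limma-voom (list adjusted p = 0.799). Kr-h1, a target of the hormone, did not pass (log2 fold change 0.59, adjusted p = 0.242), but was higher without virgin 3 (adjusted p = 0.0349), as was Jheh3, a juvenile hormone epoxide hydrolase, without virgin 1 (adjusted p = 0.0477); scaled by library size alone, 1 member was lower. Of 12 ecdysone genes, the nuclear receptor ftz-f1 fell 1.54-fold and 11 did not pass, with 1 higher and 2 lower adjusted over the list alone (list adjusted p = 0.245). In the insulin, TOR and FOXO list, bmm and the insulin-like peptide Ilp3 rose, Ilp3 by 3.98-fold, while Thor, a translation inhibitor, fell by 0.68 on the log2 scale and 10 did not pass; adjusted over the list alone, 2 were higher and 2 lower (list adjusted p = 0.286, or 0.0209 without virgin 3). That list's median was -0.07, with a mean of 0.25 and a test direction of higher. The EGFR pathway inhibitor sty rose by 0.67 on the log2 scale, 1 of 9 in its list, also adjusted over the list alone (list adjusted p = 0.186). None of 6 JAK/STAT genes passed in edgeR, DESeq2 or limma-voom, adjusted over the list alone or at an unadjusted p below 0.05 (list adjusted p = 0.601, or 0.0162 without virgin 3, where 1 gene passed), but Stat92E was lower when scaled by library size alone (log2 fold change -0.50, adjusted p = 0.0429); upd3 had 2.32 ± 2.34 and 2.83 ± 1.32 CPM. Leaving out 1 library, ftz-f1 passed only without virgin 3 (adjusted p up to 0.189 otherwise), sty only without virgin 1 (up to 0.202), and Thor was lost without virgin 1, virgin 2, mated 1 or mated 2 (up to 0.166). With RLE scaling or a filter of 1 CPM ftz-f1 did not pass (adjusted p of 0.0588 and 0.052), nor sty when scaled by library size alone (adjusted p = 0.131) or in the unstranded column (adjusted p = 0.0517).

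The stress, glycolysis and autophagy lists did not pass camera either, nor fry's mixed test. Of 7 heat shock, 13 unfolded protein, 13 glycolysis and 12 autophagy genes, 0 passed in edgeR. At an unadjusted p below 0.05 there were 3, 5, 2 and 0, DESeq2 called 3, 1, 2 and 0, and limma-voom called 0 in each. Adjusted over the list alone, 2 heat shock genes were higher and 0 passed in the other 3 lists. Scaled by library size alone, 3 glycolysis genes were lower, and with no low-count filter 2 heat shock genes were higher. List adjusted p values were 0.101, 0.0533, 0.819 and 0.929. The heat shock list passed without virgin 2 (adjusted p = 0.0087) or mated 3 (adjusted p = 0.0168) and when scaled by library size alone (adjusted p = 0.0498). The unfolded protein list passed without virgin 1 (adjusted p = 0.00139) or mated 3 (adjusted p = 0.00237), with limma-voom (adjusted p = 0.0228), with the replicate number as a block (adjusted p = 0.0491) and without the genes of other tissues (adjusted p = 0.049). The basement membrane list passed without virgin 1 (adjusted p = 0.0378), and the glutathione S-transferase list (adjusted p = 0.15) without virgin 1 (adjusted p = 0.0233) or mated 3 (adjusted p = 0.0035).

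Among the 20 genes chosen for the largest changes, Npc2c (3R, 10060252 to 10061136), of a family of sterol-binding proteins, rose from 0.326 ± 0.0120 to 5.22 ± 0.390 CPM, 15.8-fold. The neuropeptide gene CNMa rose 13.9-fold to 6.57 ± 0.705 CPM, the alkaline phosphatase Alp2 8.36-fold to 84.5 ± 26.9 CPM, and the chitinase Cht9 6.14-fold to 204 ± 39.6 CPM. CG32751 and CG6933 rose 10.1-fold and 7.57-fold. GstD2 (11.6-fold) and CG12490 (6.09-fold) completed the higher set with Uro and deltaTry, and lost their calls in some fits, GstD2 in all but that without mated 3 (adjusted p up to 0.238) and CG12490 without virgin 1, virgin 3 or mated 3 (up to 0.16); neither passed with no low-count filter, nor GstD2 with limma-voom. GstD2 rose to 7.30 ± 6.81 CPM with mated 1 the highest (4.90 and 2.00 CPM in mated 2 and 3), and its log2 fold change of 3.54 was 2.43 without mated 1 (adjusted p = 0.176). On the lower side, Eo (X, 14916756 to 14918800), an ecdysone oxidase, fell from 7.58 ± 1.59 to 0.943 ± 0.197 CPM, 8.02-fold. The synaptic protein gene cpx fell 4.65-fold, CG11878 4.26-fold and CG13360 3.49-fold. CG6012 (5.36-fold) and lncRNA:CR44779 (3.72-fold) also fell; the call of CG6012 was lost whichever library was left out (adjusted p up to 0.146), and that of lncRNA:CR44779 without virgin 2, mated 2 or mated 3 (up to 0.0972), and neither passed with limma-voom. In all, 39 of 70 named genes that passed kept their call in all 6 fits that left out 1 library.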

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

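The tests in this part were chosen after the values were seen, except the count of other splits. Chance: 353 genes passed between virgin and mated libraries and at most 0 in any of the 9 other splits of the 6 libraries into 3 and 3; the real split was the only 1 of 10 with as many, and 10 splits cannot give a share below 0.05.

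Differences were also present in the forward-strand column, which the comparison did not use, but part of them need not be separate evidence. In the forward-strand column, 40 of 2942 tested genes differed between mated and virgin libraries (28 higher, 12 lower; edgeR, adjusted p below 0.05). Of these, 12 were also called in the same direction on the reverse strand, and 8 were Jonah genes; Jon65Aiv had 3735 forward against 4915159 reverse counts over all libraries. More forward than reverse counts were held by 14 genes, 7 higher and 7 lower, among them rha (3R, 25340252 to 25344838), which overlaps the end of tobi (3R, 25344761 to 25346921) on these coordinates, and asRNA:CR44703 (2R, 21068260 to 21069445), which lies across Cht9 (2R, 21067992 to 21069286). Forward log2 fold changes of rha and asRNA:CR44703 were -3.25 and 2.66, against -2.92 for tobi and 2.62 for Cht9 on the reverse strand. Cyp4e1 (forward -1.37) likewise overlaps Mal-A1 (-1.44), and mtt (forward -2.05) overlaps Mal-A8 (-2.06). A read in such an overlap can be counted for the gene of either strand, once in each column. How many of the 40 genes this covers was not counted.

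Oocyte transcripts stood out in virgin 2. Of 15 genes of the ovary list with any count, virgin 2 was the highest library for 9, but 6 of these had drawn attention to it. Of the 9 others with a count, virgin 2 was the highest for 3 (aub, orb and bcd). That count could not settle whether ovary tissue was in that pool, since some of the 9 had almost no reads. Vm26Aa and dec-1, for example, had 0 counts in the virgin and 2 and 3 in the mated libraries. The levels of osk, yl and dhd in virgin 2 were 22.7, 29.8 and 48.7 CPM, against at most 0.127, 0.127 and 0.7 CPM elsewhere. All 192 nos and 55 bcd counts of the virgin libraries lay in virgin 2, with 4 and 0 in the mated ones. These transcripts were thus nearly confined to virgin 2. Whether ovary tissue was their source stays open. Of the eggshell genes, Cp15 had 43 counts in the virgin libraries, all in virgin 2, and Vm26Ab, Cp36 and Cp38 had 0 in every library. A larger number of midgut progenitors is argued against, since virgin 2 was the highest library for only 1 of 12 progenitor genes. Those genes do not measure division. The division genes stg, CycA and PCNA were highest in virgin 2, at 13.5, 31.2 and 7.63 CPM against at most 1.74, 6.33 and 5.07 CPM elsewhere. The oocyte transcripts were high in the same library, so these genes cannot tell more division in the midgut from ovary tissue in the pool. More division in that pool therefore stays open.

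Muscle transcripts were higher in mated samples. A smaller share of epithelium, which would raise all other tissues alike, is argued against only as far as the reference genes stand for other tissues. The muscle median exceeded that of 9 neuron and trachea genes by 0.82 (permutation p = 0.00024, 100000 resamples over genes, which are not independent). The neuron list alone had a median of -0.24 and the trachea list one of -0.06. Only 4 of 8 neuron genes could be tested, and whether these are transcribed in the epithelium too was not examined. Flight muscle carried into the pools is argued against by Act88F, the main actin of that tissue, whose rise was 0.0854% of that of Mhc. An equal rise of all sarcomere genes is argued against: with the common level of the other 9 taken out of each library, 3 of 10 sarcomere genes still differed between the groups, Act57B and Act87E lying above it by 0.62 and 0.85 and sls below it by 0.69 on the log2 scale (edgeR, adjusted p over the 10 genes up to 0.011). That test replaced a chi-square for heterogeneity (49.2 on 9 degrees of freedom) and an exact permutation test over the 10 splits, which could give no p below 0.1. Unequal rises do not exclude a larger share of muscle as the whole cause, since a gene also transcribed in other cells would rise less under it. A larger share of muscle taken at dissection, alone or beside changes in single genes, and a difference with mating, stay open.

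Ribosomal protein transcripts were lower in mated samples. Dilution by the rising proteases is argued against, since none of 10000 random lists matched on abundance had a median as low as -0.43 (lowest 0.01, median 0.14), which sets the share at its floor of 0.0001. Under-counting of short transcripts is argued against in the same way, with a lowest median of -0.06 over 10000 lists matched on exonic length and abundance for the 82 genes with a length, again at the floor of 0.0001. Random lists ignore the correlation between ribosomal genes, and coordinated variation between pools cannot be told apart from an effect of mating with 3 against 3 libraries (exact permutation p of the mean level = 0.1, two-sided). A difference with mating stays open.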

How the results depend on the processing

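No gene was called in the opposite direction in any fit; the trypsin list kept its call under library-size scaling while its median turned from 0.20 to -0.06. The 353 genes (213 higher, 140 lower) stayed within 1.5 times under RLE and upper-quartile scaling, both filters, limma-voom, the unstranded column and without other-tissue genes. Library size alone gave 872 (146 and 726; the larger fall follows the median shift from -0.05 to -0.30) and DESeq2 603 (375 and 228), including all 353; the cause was not tested. A threshold of 0.01 gave 134 (89 and 45) and a minimum fold of 1.5 gave 80 (55 and 25), both stricter by construction. Leaving out 1 library gave 169 to 308 genes (118 to 208 higher, 51 to 100 lower) and 10 to 15 lists, with fewer samples per fit. Without virgin 2 and mated 1 together, chosen after seeing the data, 191 passed (114 and 77; 152 shared) with 9 lists. An estimated correlation kept 0 of the 11 lists; fry passed 7 lists, 5 of them among the 11, with neurons and the peritrophic matrix added. With the replicate number as a block, 290 genes passed (194 and 96, with 260 shared) and 12 lists. Of 125 genes followed one by one, 14 lost their call with it, among them tobi and Mal-A8 (adjusted p of 0.101 and 0.129). The labels do not say whether the numbers pair the samples. Same-numbered libraries had correlations of deviations of -0.155, -0.0496 and -0.0272, which show no pairing but cannot exclude it. At 1.5-fold, 2% of simulated changes were recovered.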

Other observations

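The genes and families here were chosen after their values were seen, so the counts per family are given without a test. Alkaline phosphatases, enzymes of the gut brush border and other membranes, were higher for 5 of 8 tested genes, with Alp9 (3L, 5595542 to 5597422) from 313 ± 64.0 to 1809 ± 215 CPM and its neighbour Alp10 (3L, 5592741 to 5595272) from 356 ± 48.2 to 1898 ± 282 CPM (SD, n = 3 each); Alp2 rose too, as did Alp5 (log2 fold change 0.68) and Alp6 (0.65). Alp5 lost its call without virgin 2, virgin 3 or mated 3 (adjusted p up to 0.0708), and Alp6 without virgin 3 or mated 3 (up to 0.0576) or when scaled by library size alone (adjusted p = 0.0539). UDP-glycosyltransferases, which attach sugars to small molecules, were lower for 6 of 30 genes and higher for 0, with Ugt303A1 at 162 ± 26.1 and 57.1 ± 10.6 CPM and Ugt304A1 at 68.9 ± 2.75 and 28.6 ± 6.80 CPM.

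Of 8 troponin C, Zasp, Mp20, Prm and Mlp84B genes, 7 were higher and 1 did not pass; TpnC73F is also in the fixed muscle list. Mlp84B rose 2.54-fold, TpnC47D 2.26-fold and Mp20 1.75-fold.

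The channel gene trp had 0 counts in all virgin libraries and 34, 68 and 77 counts in the mated ones, at least 84.4-fold higher against a floor of 3 counts over the group, and passed in all 6 fits that left out 1 library. Transcripts above 5 CPM and over 8-fold above every other library numbered 24 in virgin 2, 7 in mated 1, 1 in mated 2 and 0 in the other 3. In mated 1 they included CG11893, at 91.1 CPM against at most 0.167 CPM elsewhere, and lncRNA:roX1, a noncoding RNA of dosage compensation in males, at 41.4 CPM against at most 0.528 CPM, while lncRNA:roX2 had 1 count there.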
